A study of Homo sapiens with 13 samples.

How the data were processed

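Total RNA of 13 human cell cultures was measured on Affymetrix U133 X3P arrays, which carry 61359 probe sets. Per the labels' protocols, cells were grown in Gelfoam, a gelatin sponge, AD-MSC for 2 to 3 weeks and, per the design text, disc cells for 2 weeks. The AD-MSC were grown with or without TGF-β3, whose dose the labels give as 10 ng/nl. That unit is taken over as labelled and could not be checked. RNA was extracted with Trizol, amplified in 2 rounds of transcription and labelled with biotin, per the labels and the design text. The deposited values are the authors' processed probe set values on a log2 scale, with no centring per probe set. The submitters' processing notes name GCOS, MAS5, GCRMA and RMA without a role or order, so it is unknown which of these methods made the values. No date or batch of hybridization was given.

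Samples were grouped by their labels into control AD-MSC (n = 3), TGF-β3 AD-MSC (n = 3) and disc cells (n = 7). Values were used as deposited because the array medians spanned 0.15 log2 units, under the 1 unit set as the limit for quantile normalization. Probe sets were named from the array annotation and a reference gene table. Of the probe sets, 44538 had exactly 1 gene symbol and were used, 1492 with several symbols and 15329 without a gene were left out, and 85 probe sets of sex-linked genes were left out. Each gene was represented by its probe set with the highest mean over the 13 arrays, which gave 19509 genes. A gene was tested if at least 3 of the 13 arrays exceeded 4.21, the median of all values, which kept 13497 genes.

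The 3 group comparisons were made in 1 fit with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 13 arrays, so that the groups shared 1 estimate of the spread (10 residual degrees of freedom). Calls required a Benjamini-Hochberg adjusted p under 0.05, two-sided, and SEs are moderated. Gene lists, 22 in number with 581 genes of which 481 were tested, were fixed in advance and tested with limma's camera at a preset inter-gene correlation of 0.01. An estimated correlation was used beside it, with which 4 of the 32 list calls held, and adjusted p ran over the lists within a comparison. Of the listed genes, 35 had no probe set with exactly 1 symbol. In called lists the median, the mean and the camera direction shared their sign, and among uncalled lists they differed in 2, 4 and 2 lists of the TGF-β3, the disc against control and the disc against TGF-β3 comparison.

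Most genes named in the text were taken by a rule. Per comparison, it took the 8 highest and 8 lowest log2 changes. Only passing genes whose groups did not overlap and whose higher mean exceeded the median of all values were eligible for these. It also took up to 4 members of each list with the smallest p. Last came 10 anchor genes of cartilage, matrix and TGF-β biology, of which 7 were tested. Not every gene taken by the rule is printed. Further genes were named outside this rule. Among them are members of the additional marker lists, examples of leukocyte genes, and genes with probe sets called in both directions. The leukocyte examples and the genes with such probe sets were picked from the results. Genes that differ between persons were never named. The rule, the comparisons and most alternatives were set before the data were examined.

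The AD-MSC arrays carry culture numbers shared by a control and a treated array, per the sample labels. Deviations from the group means correlated within a culture (0.43 in A, 0.34 in B and 0.41 in C, across genes) more than between different cultures (-0.34 to 0.02). The numbers therefore paired the samples, and the TGF-β3 comparison was also fitted with the culture as a block, on the 6 AD-MSC arrays and, by duplicateCorrelation, on all 13. Nearness to disc cells was measured per culture as the Euclidean distance to the mean of the disc arrays, and as a covariance of the culture's TGF-β3 effect with the disc difference from the other cultures' controls. Simulated no-effect values for comparisons with shared controls came from 100 data sets with the measured means and spread and no TGF-β3 effect. Their noise was drawn independently for each gene and array, without the pairing by culture.

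The steps were tested on simulated data with the real spread over 13497 genes, with 67 changed 2-fold, 67 changed 4-fold and 66 changed 16-fold in each comparison. In the TGF-β3 comparison 17.9% of 2-fold, 65.7% of 4-fold and 92.4% of 16-fold changes were called, with 7 false calls. In the comparison of disc cells with controls these shares were 22.4%, 80.6% and 98.5%, with 6 false calls, and in that of disc cells with TGF-β3 AD-MSC 17.9%, 79.1% and 93.9%, with 3 false calls. Alternatives covered quantile and median scaling, other filters, other choices of probe set, only the groups compared, array weights, an intensity trend, stricter thresholds, limma's fry for the lists (which tests whether a list's genes move one way), the culture block, and leaving out each array or AD-MSC culture. Pseudocounts did not apply to values that are already logarithms. Additional marker lists for macrophages (45 genes), lymphocytes (25), mast cells (12) and a second endothelial list (23) were written before their values were looked at.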

Results

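Gene expression was measured on 13 Affymetrix U133 X3P arrays of human cells grown in a 3-dimensional gelatin sponge. Adipose-derived mesenchymal stem cells (AD-MSC), multipotent stromal cells of fat, came from 3 cultures, called A, B and C here. Each AD-MSC culture gave 1 control array and 1 array with transforming growth factor β3 (TGF-β3), a factor used to drive stromal cells toward cartilage. The other 7 arrays came from 7 cultures of annulus cells of the intervertebral disc, called D1 to D7. Array medians of the deposited log2 values lay between 4.14 and 4.29, and 13497 genes were tested. The number of arrays limits the precision of every value. No detection calls were used. A group mean below 4.21, the median of all values, is not shown to lie above background, so a log2 difference from such a group depends on the background level, which its SE does not cover. The labels do not state whether the cultures came from separate donors, so the p-values measure only the spread between these samples.

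Pairwise correlations across genes ranged from 0.95 to 0.97 among the control AD-MSC, from 0.95 to 0.98 among the TGF-β3 AD-MSC, and from 0.86 to 0.97 among the disc arrays. Genes are not independent replicates in these correlations. The first principal component held 50.2% of the variance and separated disc cells from AD-MSC. The second held 14.1%, and on it culture D1 scored 117.7 while the other 6 disc cultures scored from -30.7 to -20.3.

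**Figure D1:**
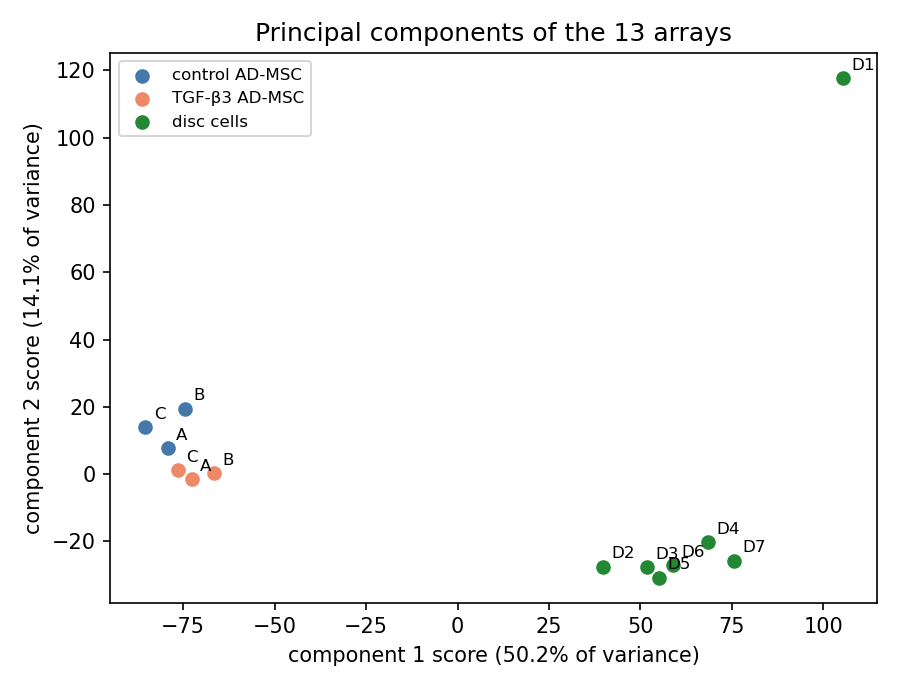
Scores of the 13 arrays on the first and second principal components, with the percent of variance on each axis; each point is 1 array, labelled with its culture. Disc cells lie to the right of AD-MSC on component 1, and D1 lies at 117.7 on component 2.

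The first comparison asked what TGF-β3 changed in AD-MSC (3 treated and 3 control arrays). COL10A1, the collagen X gene of hypertrophic cartilage, rose by 5.77 on the log2 scale (SE 0.64, 54.7-fold, adjusted p = 0.00068). KANK4 rose by 5.02 (SE 0.64), the sialyltransferase gene ST6GAL2 by 4.68 (SE 0.64), HAPLN1, which encodes the link protein of aggrecan aggregates, by 4.06 (SE 0.70), and the proenkephalin gene PENK by 3.79 (SE 0.53). MMP12, the macrophage metalloelastase, fell by 6.84 on the log2 scale (SE 0.66, 114-fold, adjusted p = 0.00025). FCGBP fell by 4.39 (SE 0.37), RCSD1 fell by 3.74 (SE 0.30), the lectin gene CD209 fell by 3.64 (SE 0.37), and the costimulatory receptor gene CD28 fell by 3.51 (SE 0.42) on the log2 scale. Means were below 4.21 in controls for ST6GAL2 and with TGF-β3 for RCSD1, CD209 and CD28. With the mean of a gene's probe sets RCSD1 had -1.91 and CD209 had -1.83.

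Among 23 measured genes of cartilage matrix and its regulators, HAPLN1 and MATN3 (log2 change 3.04, SE 0.63) rose and 21 did not pass. Adjusted over the list alone, 5 rose and 1 fell, and the list was called upward (adjusted p = 0.022, and adjusted p = 0.24 with an estimated correlation). Its median log2 change was 0.05 against a mean of 0.61, so part of its members carried the shift. SOX9, the transcription factor that drives cartilage formation, had a log2 change of 2.66 (SE 0.68, adjusted p = 0.10), and the aggrecan gene ACAN had -2.41 (SE 1.04, adjusted p = 0.49). ACAN ranged from -3.75 without treated A to -1.39 without culture B, with -1.47 without treated B and -1.53 with the mean of its probe sets, and passed with array weights (-3.13, adjusted p = 0.018). COMP had a log2 change of 1.26 (adjusted p = 0.96, and 0.77 without control B and 0.79 without culture B), and COL1A1 and DCN, both with control means of at least 14.8, had changes of 0.03 and 0.00. Of 17 measured genes of bone and hypertrophic cartilage, COL10A1 rose and 16 did not pass. Adjusted over the list alone 6 rose and 2 fell (list adjusted p = 0.0022, and adjusted p = 0.068 with an estimated correlation). MMP13, a collagenase of hypertrophic cartilage, had a log2 change of 5.63 (SE 1.53, adjusted p = 0.13) from a control mean below 4.21. The list of 30 TGF-β response genes shifted upward (adjusted p = 2.0e-05, and adjusted p = 0.21 with an estimated correlation) although no member passed, and adjusted over the list alone 1 rose. IL11 in that list had a log2 change of 3.71 (SE 0.93, adjusted p = 0.10), and CDKN2B one of 2.22 (SE 0.66, adjusted p = 0.18). Of 37 measured TGF-β and BMP ligands, receptors and antagonists, the co-receptor gene TGFBR3 fell by 2.68 on the log2 scale (SE 0.44) and 36 did not pass, with 2 higher and 2 lower adjusted over the list alone.

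Leukocyte markers fell as a list (adjusted p = 2.2e-15, and adjusted p = 0.068 with an estimated correlation). Of 19 measured, 4 fell and 15 did not pass, and adjusted over the list alone 12 fell. C1QA, a complement subunit made by macrophages, fell by 2.19 on the log2 scale (SE 0.28), CD48 fell by 3.06 (SE 0.45, and -1.62 with the mean of its probe sets), AIF1 fell by 2.45 (SE 0.38), and CSF1R, the receptor for macrophage colony-stimulating factor, fell by 2.76 (SE 0.59). LYZ, the lysozyme gene, was near 11.2 in both groups. The proliferation list fell (adjusted p = 1.4e-12, and adjusted p = 0.23 with an estimated correlation). CDK1, the kinase of entry into mitosis, fell by 2.43 on the log2 scale (SE 0.47, but -1.45 with the mean of its probe sets, adjusted p = 0.083), 29 of 30 members did not pass, and adjusted over the list alone 3 fell. No member passed in the lists of 25 inflammatory mediators (adjusted p = 4.1e-06, and adjusted p = 0.21 with an estimated correlation), 14 endothelial markers (adjusted p = 5.0e-06, then adjusted p = 0.22 with an estimated correlation), 11 pericyte and smooth muscle markers (0.0022, then adjusted p = 0.17 with an estimated correlation) and 19 stem cell surface markers (0.0031, then adjusted p = 0.17 with an estimated correlation), all shifted downward. Adjusted over the list alone 2 genes fell in each of these 4 lists. The endothelial genes CLDN5 and EMCN had log2 changes of -2.58 (adjusted p = 0.12) and -1.96 (adjusted p = 0.062). The stem cell surface gene CD34 had -3.04 (adjusted p = 0.15), and the chemokine gene CCL2 had -1.85 (adjusted p = 0.15). The hypoxia list (25 measured, adjusted p = 0.022, then adjusted p = 0.57 with an estimated correlation) and the adipocyte list (23 measured, adjusted p = 0.042, then adjusted p = 0.24 with an estimated correlation) also shifted downward. No member of these 2 lists passed, and 2 and 1 fell adjusted over the list alone. LPL, the lipoprotein lipase gene of adipocytes, had a log2 change of -3.33 (adjusted p = 0.11). The other 11 lists were not called (adjusted p from 0.054 to 0.96), and CAV1 in the nucleus pulposus list fell by 1.28 on the log2 scale (SE 0.22).

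In total 122 genes passed in limma (32 higher and 90 lower), all of them changed the same way in the 3 cultures, and 85 changed at least 4-fold. With the culture as a block on the 6 AD-MSC arrays, 574 genes passed (152 higher and 422 lower), 106 of the 122 among them. Then 10 leukocyte, 8 proliferation, 6 endothelial, 4 pericyte, 4 adipocyte, 3 stem cell surface and 1 inflammatory list genes were lower, with 0 higher. Cartilage genes had 6 higher and 2 lower, and TGF-β and BMP ligands, receptors and antagonists 4 and 5. Bone and TGF-β response genes had 4 and 2 higher, with 0 lower, and hypoxia genes had 0 either way. In that fit SOX9 (adjusted p = 0.016), MMP13 (0.013), IL11 (0.021), CDKN2B (0.029), CLDN5 (0.026), EMCN (0.036), CD34 (0.013), CCL2 (0.025) and LPL (0.012) passed as well, and the contractile and myofibroblast list was called upward (adjusted p = 0.016, against 0.10 on 13 arrays, and adjusted p = 0.38 with an estimated correlation) with no member higher and 1 lower. The count of 122 was 211 without control A, 62 without control B, 58 without treated B, 79 without D3 or without D4, 42 without both arrays of B, and 64 without both arrays of C. Of these 16 fits that leave out 1 array or 1 AD-MSC culture, the call was lost in 14 for MATN3, 12 for CSF1R, 10 for CDK1, 5 for HAPLN1 and CAV1, 3 for TGFBR3 and 2 for ST6GAL2. List calls were lost for cartilage genes without treated A (adjusted p = 0.14), stem cell surface markers without treated B (0.076), hypoxia genes without control A or treated C (up to 0.33), and adipocyte genes without treated A or B, control B or C, or D1 (up to 0.12). The gene call was also lost for KANK4, C1QA and AIF1 without culture B (adjusted p = 0.056, 0.054 and 0.13) and for PENK and CD48 without culture C (0.067 and 0.056). With only the 2 groups compared, 94 genes passed (40 higher and 54 lower), 38 of the 122 among them. In that fit the calls of HAPLN1, MATN3, CD28, C1QA, CD48, AIF1, CSF1R, TGFBR3 and CAV1 were lost (adjusted p = 0.053 or above). The call of CSF1R was also lost with quantile normalization, median centring, no filter, every probe set and array weights (-1.79), that of MATN3 with quantile normalization, no filter and every probe set, that of CDK1 with the stricter filter and that of AIF1 without x_at probe sets. Cartilage and adipocyte list calls were lost with array weights and with fry, and with fry also those of the endothelial, hypoxia, inflammatory, stem cell surface, pericyte, proliferation and TGF-β response lists.

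**Figure D2:**
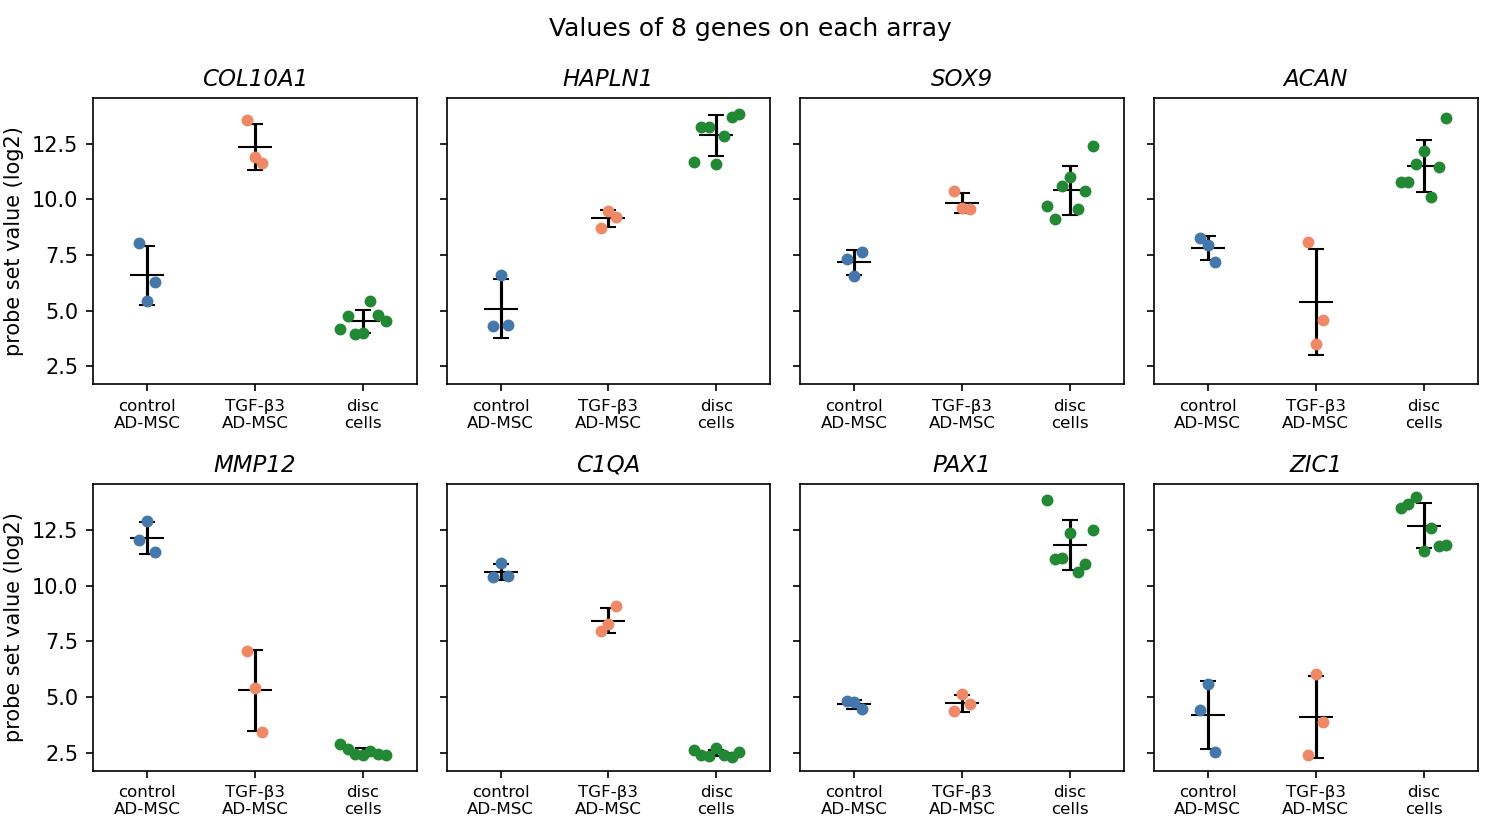
Probe set values (log2) of 8 genes in control AD-MSC, TGF-β3 AD-MSC and disc cells; points are arrays, and the bars show the mean and SD. COL10A1 lay at 12.4 on average with TGF-β3 against 6.59 in controls and 4.53 in disc cells, while PAX1 averaged 11.8 in disc cells and 4.67 in controls.

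The second comparison set the 7 disc cultures against the 3 control AD-MSC. The transcription factor gene ZIC1 was higher in disc cells by 8.52 on the log2 scale (SE 0.82, but 3.84 with the mean of its probe sets), the protease inhibitor gene SLPI by 7.92 (SE 0.62), HAPLN1 by 7.79 (SE 0.59), FGFBP2 by 7.22 (SE 1.21) and PAX1, a transcription factor of the embryonic sclerotome, by 7.14 (SE 0.56). PENK was higher by 6.79 (SE 0.45), CCN6 by 6.67 (SE 0.82) and the urea transporter gene SLC14A1 by 6.57 (SE 0.89). MMP9, a gelatinase, had a log2 difference of -11.13 (SE 0.54), the osteopontin gene SPP1 -10.94 (SE 0.77), the chemokine receptor gene CXCR4 -9.94 (SE 0.44) and MMP12 -9.60 (SE 0.56). Adjusted p was at most 0.0012 for each of these genes. Means were below 4.21 in controls for ZIC1, SLPI, FGFBP2, CCN6 and SLC14A1, and in disc cells for MMP9, SPP1, CXCR4 and MMP12. With the mean of its probe sets SPP1 had -6.66.

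Cartilage genes were higher in disc cells as a list (adjusted p = 0.0043, and adjusted p = 0.21 with an estimated correlation). Of 23 measured, 8 were higher, 1 was lower and 14 did not pass, and adjusted over the list alone 9 were higher and 1 lower. ACAN was higher by 3.70 (SE 0.88, and 2.40 with the mean of its probe sets), SOX9 by 3.22 (SE 0.57), the collagen-binding integrin gene ITGA10 by 4.26 (SE 0.41) and the matrilin gene MATN2 by 4.96 (SE 0.68). COL10A1 was lower, with a log2 difference of -2.07 (SE 0.54), and COMP had -2.12 (SE 0.89, adjusted p = 0.10, and -1.38 with array weights). DCN (0.43, adjusted p = 0.17, and 0.90 with the mean of its probe sets), TGFBI (0.48, adjusted p = 0.084, and 0.30 without control B) and COL1A1 (-0.02, adjusted p = 0.95) did not pass, although with the mean of its probe sets COL1A1 had -1.49 (adjusted p = 0.0066). The nucleus pulposus and notochord list was higher (adjusted p = 0.046, and adjusted p = 0.21 with an estimated correlation), with 6 of 19 higher and 1 lower both over all genes and adjusted over the list alone. Its median difference was 0.30 against a mean of 1.11. PAX1, given above as a sclerotome gene, is a member, so the list does not stand for nucleus pulposus or notochord cells alone. FOXF1 in this list was higher by 4.63 (SE 1.02), with D2 at 4.53 and the other 6 disc cultures at 8.34 or above. The annulus, tendon and ligament list was not called (adjusted p = 0.43), with 5 of 19 higher and 2 lower by either adjustment. The tendon regulator gene MKX was higher by 3.97 (SE 0.77), with D2 at 4.94 against at least 7.73 in the others, and the Wnt antagonist gene SFRP2 had a log2 difference of -8.04 (SE 0.57). Control means of FOXF1 and MKX were below 4.21, and MKX had 2.47 with the mean of its probe sets.

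Leukocyte markers were lower in disc cells as a list (adjusted p = 3.1e-18, and adjusted p = 0.050 with an estimated correlation). Of 19 measured, 15 were lower by either adjustment and 4 did not pass. Log2 differences were -8.14 for C1QA (SE 0.24), -9.19 for the signalling adaptor gene TYROBP (SE 0.47), -8.82 for the haemoglobin scavenger receptor gene CD163 (SE 0.46) and -7.87 for LYZ (SE 0.38). Endothelial markers were lower as well (adjusted p = 5.0e-07, and adjusted p = 0.21 with an estimated correlation), with 10 of 14 lower, and 11 adjusted over the list alone. CLDN5 had -7.81 (SE 0.58), VWF, the von Willebrand factor gene, had -5.74 (SE 0.56) and EMCN had -5.12 (SE 0.37). Matrix proteases and inhibitors were lower (adjusted p = 0.0023, and adjusted p = 0.050 with an estimated correlation), with 13 of 37 lower and 2 higher, and 15 and 2 adjusted over the list alone. MMP11 had -5.43 (SE 0.27), and -1.05 with the mean of its probe sets. Disc means of C1QA, TYROBP, CD163, LYZ, CLDN5, EMCN and MMP11 were below 4.21, and VWF had -3.01 with the mean of its probe sets. Of these proteases, MMP9 and MMP12 are known macrophage products.

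Adipocyte genes were lower (adjusted p = 0.012, and adjusted p = 0.21 with an estimated correlation), with 10 of 23 lower and 1 higher by either adjustment, including LPL (-6.48, SE 0.73) and SCD, a fatty acid desaturase gene (-3.10, SE 0.34). Other proteoglycans and matrix glycoproteins were lower (adjusted p = 0.0040, and adjusted p = 0.33 with an estimated correlation), with 11 of 39 lower, 12 adjusted over the list alone, and FBLN5, an elastic fibre gene, at -4.07 (SE 0.57). Hypoxia response genes were higher (adjusted p = 0.0039, and adjusted p = 0.42 with an estimated correlation), with 7 of 25 higher, 9 adjusted over the list alone, and ANGPTL4 higher by 3.52 (SE 0.43). Weaker list shifts were those of pericyte markers (lower, adjusted p = 0.026, and 0.26 with an estimated correlation), contractile genes (lower, 0.036 and 0.42), collagens outside the cartilage list (lower, 0.041 and 0.58), HOX genes (higher, 0.038 and 0.42) and proliferation genes (higher, 0.036 and 0.77). In these lists 5 of 11, 9 of 24 and 9 of 24 were lower, and 2 of 20 and 4 of 30 were higher. The other way went 1 pericyte marker, 1 contractile gene and 2 collagens, and none in the HOX and proliferation lists. Adjusted over the list alone the counts were 5, 9, 9, 2 and 0, and 1, 2 and 2 the other way in the first 3 lists. COL8A1 among the collagens was higher by 2.36 (SE 0.33, and 1.29 with the mean of its probe sets). Inflammatory mediators went both ways (5 of 25 higher and 6 lower, and 7 lower adjusted over the list alone). The prostaglandin synthase gene PTGS2 was higher by 4.39 (SE 0.35) and the chemokine gene CXCL6 by 6.01 (SE 0.76), and IL1RN had -7.06 (SE 0.60, and -2.48 with the mean of its probe sets), with D1 at 5.44 and the other 6 disc cultures at most at 3.79. Stem cell surface markers also went both ways, with NT5E higher by 2.60 (SE 0.31) and CD34 at -5.45 (SE 0.73), its disc mean below 4.21 like that of IL1RN. Among TGF-β and nerve growth genes, TGFB2 was higher by 4.64 (SE 0.56, and 2.32 with the mean of its probe sets) and BDNF, a neurotrophin gene, by 4.29 (SE 0.42). Lists with members on both sides and no call were TGF-β response genes (7 of 30 higher and 4 lower, adjusted p = 0.072), nerve and neurotrophin genes (6 of 17 and 4, 0.19), small leucine-rich proteoglycans (2 of 12 and 2, 0.66), matrix crosslinking genes (4 of 24 and 2, 0.67), TGF-β and BMP ligands, receptors and antagonists (7 of 37 and 7, 0.90), and bone and hypertrophic cartilage genes (2 of 17 and 5, 0.90). Inflammatory mediators and stem cell surface markers had adjusted p = 0.89 each.

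In total 3124 genes passed (1283 higher and 1841 lower in disc cells), and 3305 with quantile normalization, of which 51.3% were higher against 41.1%. Without control C 1744 genes passed. The call was lost for ACAN without control C (adjusted p = 0.055) and for COL10A1 without control A (log2 difference -1.35, adjusted p = 0.096). List calls were lost for pericyte markers without D1 (adjusted p = 0.054), for contractile genes without control A or C (up to 0.093), for HOX genes without control B, control C or D4 (up to 0.12), for collagens without control A or C or D4, D5, D6 or D7 (up to 0.28), for nucleus pulposus markers without control A or C, treated A, D3, D4 or D5 (up to 0.082), and for proliferation genes without control A or C, D1, D2, D3 or D4 (up to 0.15). The nucleus pulposus call was also lost with quantile normalization, each array centred on its median, no filter, the mean of a gene's probe sets and array weights. Array weights also ended the calls of pericyte markers, proliferation genes and collagens, no filter those of proliferation and HOX genes, the stricter filter those of collagens and HOX genes, the mean of probe sets that of pericyte markers, and fry those of HOX and proliferation genes.

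**Figure D3:**
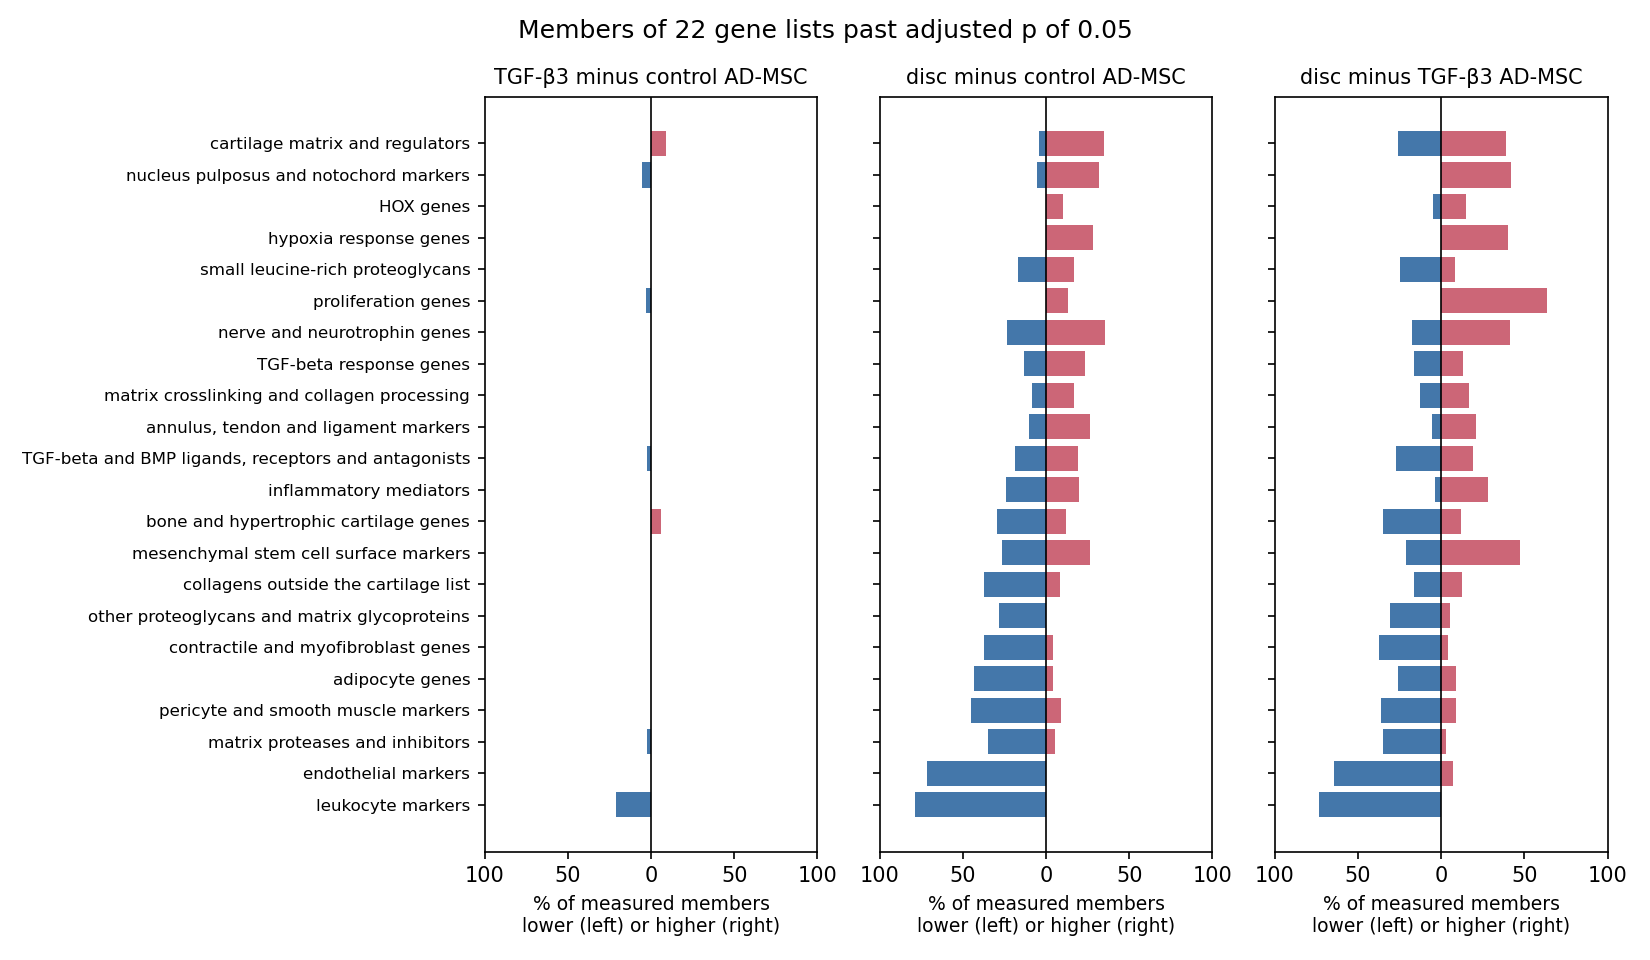
Percent of the measured members of 22 gene lists that passed an adjusted p of 0.05, lower to the left and higher to the right, in the 3 comparisons (13 arrays in 1 fit). With 15 of 19 lower, leukocyte markers stood out in disc cells against controls, and 19 of 30 proliferation genes were higher in disc cells than in TGF-β3 AD-MSC.

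The third comparison set the 7 disc cultures against the 3 TGF-β3 AD-MSC. CLEC3B, the tetranectin gene, was higher in disc cells by 9.22 on the log2 scale (SE 1.27), with D1 at 5.99 and the other 6 disc cultures at 11.2 or above. ZIC1 was higher by 8.60 (SE 0.82, but 3.89 with the mean of its probe sets), SLPI by 7.89 (SE 0.62), FGL2 by 7.53 (SE 0.52), CHI3L2 by 7.31 (SE 0.94) and PAX1 by 7.09 (SE 0.56). The osteoprotegerin gene TNFRSF11B was higher by 7.65 (SE 0.83) and CXCL6 by 7.64 (SE 0.76), and D1 had the lowest disc value of both. SPP1 (-10.16, SE 0.77), MMP9 (-9.12, SE 0.54), SFRP2 (-8.72, SE 0.57), COL10A1 (-7.84, SE 0.54) and KANK4 (-7.70, SE 0.54) were lower in disc cells. Means were below 4.21 with TGF-β3 for CLEC3B, ZIC1, SLPI, FGL2, CHI3L2 and CXCL6, and in disc cells for SPP1 and MMP9. With the mean of its probe sets SPP1 had -5.56.

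Proliferation genes were higher in disc cells than in TGF-β3 AD-MSC (adjusted p = 6.5e-09, and adjusted p = 0.34 with an estimated correlation). Of 30 measured, 19 were higher, 23 adjusted over the list alone, and none was lower. CDK1 was higher by 3.93 (SE 0.40, and 2.48 with the mean of its probe sets), NUSAP1 by 3.78 (SE 0.57) and the topoisomerase gene TOP2A by 2.58 (SE 0.43). The cartilage list was not called (adjusted p = 0.15), with 9 of 23 higher and 6 lower, and 10 and 7 adjusted over the list alone. ACAN was higher in disc cells by 6.12 (SE 0.88, and 3.93 with the mean of its probe sets), ITGA10 by 4.62 (SE 0.41) and MATN2 by 5.38 (SE 0.68), while COMP was lower (-3.38, SE 0.89) and SOX9 had 0.55 (SE 0.57, adjusted p = 0.50, with 1.03 by array weights and 0.22 without D7). The nucleus pulposus and notochord list was higher (adjusted p = 0.0021, and adjusted p = 0.046 with an estimated correlation), with 8 of 19 higher, 9 adjusted over the list alone. Its median difference was 0.94 against a mean of 1.44, and PAX1 and FOXF1 are members of it. Hypoxia response genes were higher (adjusted p = 2.0e-05, and adjusted p = 0.33 with an estimated correlation), with 10 of 25 higher, 11 adjusted over the list alone, and ANGPTL4 higher by 4.29 (SE 0.43).

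Leukocyte markers were lower in disc cells than in TGF-β3 AD-MSC too (adjusted p = 2.9e-12, and adjusted p = 0.084 with an estimated correlation), with 14 of 19 lower by either adjustment. C1QA had a log2 difference of -5.95 (SE 0.24) and LYZ one of -7.84 (SE 0.38). Endothelial markers (9 of 14 lower and 1 higher by either adjustment) were lower, with adjusted p = 0.00024, and adjusted p = 0.33 with an estimated correlation, and CLDN5 had -5.24 (SE 0.58). Matrix proteases (13 of 37 lower and 1 higher, and 15 and 2 adjusted over the list alone) were lower, with adjusted p = 0.00053, and adjusted p = 0.046 with an estimated correlation, and MMP11 had -6.00 (SE 0.27), or -1.19 with the mean of its probe sets. Other proteoglycans and matrix glycoproteins (12 of 39 lower and 2 higher, and 13 and 2 adjusted over the list alone) were lower, with adjusted p = 0.0017, and adjusted p = 0.33 with an estimated correlation. Contractile genes (9 of 24 lower and 1 higher by either adjustment) were lower, with adjusted p = 0.0035, and adjusted p = 0.33 with an estimated correlation, and the calponin gene CNN1 had -4.67 (SE 0.63). CDKN2B, a cell cycle inhibitor gene, had -5.01 (SE 0.56). The other 14 lists were not called (adjusted p from 0.058 to 0.87). In total 3419 genes passed (1510 higher and 1909 lower). With quantile normalization 3488 passed, of which 54.8% were higher against 44.2%, and without treated C 1879 passed and COMP did not (adjusted p = 0.065).

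The last comparison asked whether TGF-β3 brought AD-MSC nearer to disc cells. Over all genes the Euclidean distance to the disc mean changed with TGF-β3 by 2.43 in culture A, -11.73 in B and -8.53 in C, from a mean of 158.2 in controls. An exact two-sided sign-flip permutation test gave p = 0.5, and 0.25 is the smallest p that 3 cultures allow. In an analysis chosen after the data were seen, the change was -19.3 in A, -27.4 in B and -21.6 in C over genes called lower in disc cells than in the other cultures' controls. Over genes called higher it was -0.63 in A, 6.53 in B and -2.53 in C, which gives no common direction. The effect of TGF-β3 in each culture covaried with the disc difference measured against the other cultures' controls, with a mean covariance of 0.25 (SD 0.0073, n = 3). The 3 covariances share the disc mean and, in pairs, a control array, so their SD does not measure independent replication. Leaving out 1 array gave means of 0.20 to 0.29. Of the 90 genes that TGF-β3 lowered, 80 were also lower in disc cells than in controls, MMP12, C1QA and CD48 among them, where the product of the counts over all genes gives 12.3. The 4 leukocyte markers that fell with TGF-β3 were all among these 80, beside further genes known from leukocytes such as PLEK, CD209, CD28, CD4, ITGAX, CYBB, SYK and PTPN6. The further genes are examples picked from the 80, and no count or test of leukocyte genes among the 80 was made. The part of leukocyte genes in the nearness to disc cells was not separated. Of the 32 it raised, 9 were higher in disc cells, HAPLN1 and PENK among them (3.04 by the same product), and 8 were lower, COL10A1 and KANK4 among them (4.36). Of the genes lowered, 5 were higher in disc cells (8.56), CDK1 and CAV1 among them. Because the comparisons share their controls, data simulated without a TGF-β3 effect gave a covariance between both comparisons of 0.13 against 0.30 measured, and a correlation across genes of 0.20 against 0.34. The simulated data had no pairing of arrays by culture and no correlation between genes. On average they called 1866 genes higher and 2386 lower in disc cells, against 1283 and 1841 measured. Their no-effect values are thus approximate. These simulations called at most 1 gene for TGF-β3 in either direction, so their shared counts (0.03 higher and 0.01 lower in both, on average) are near 0 by construction. The products leave out the shared controls, and part of the excess over them can come from those. They also leave out that the groups shared 1 estimate of the spread per gene. A gene that varied little among the disc arrays, such as one near background there, had that estimate lowered for both comparisons. Such a gene could thus pass more easily in both, and the part of the 80 that this accounts for was not tested.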

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

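The correlation of disc culture D1 with the AD-MSC arrays, and the use of CCL18 and LYZ below, were chosen only after the results were seen. Disc values of 81 named genes and 18 measures of the disc arrays were checked for a culture far from the other 6, by Dixon's ratio of the gap to the whole range. Chance alone passes about 1 in 20, or 4.05 genes and 0.9 array measures, and 11 genes and 7 measures passed. The array measures are not independent of each other. All 7 that passed concern D1, and several restate its distance from the other arrays, so 7 does not count separate findings. D1 stood apart in 6 genes. Its ratio was 0.937 for IL1RN, 0.698 for CLEC3B, 0.642 for TNFRSF11B, 0.614 for CD28, 0.579 for CXCL6 and 0.576 for MATN3. D2 stood apart low in MKX (0.614) and FOXF1 (0.584), D4 high in RNASE1 (0.657) and VWF (0.652), and D5 high in SPP1 (0.651). The ratio does not measure size. Disc values all lay below 4.21 for CD28 (2.80 in D1, 2.55 to 2.64 in the others) and RNASE1 (3.55 in D4, 2.84 to 3.08 in the others). These 2 genes are thus not shown to differ above background.

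D1 also stood apart in 7 array measures. The ratio was 0.929 for the score on component 2, 0.776 for the number of genes off by at least 4-fold from the other disc cultures (1458 in D1 and 138 to 434 in the others), 0.755 for the mean correlation with the other disc arrays (0.877 in D1), 0.690 for the SD of its deviations, and 0.572 for the upper quartile of all values (6.83 in D1 and at least 7.03 in the others). It was 0.744 for the correlation of deviations between 2 probe sets of a gene, and 0.663 for the mean correlation with the AD-MSC arrays.

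An AD-MSC array carrying a disc label was argued against. D1 correlated at 0.863 to 0.893 with the other disc arrays and at 0.763 to 0.784 with the AD-MSC arrays. Its mean correlation with the AD-MSC arrays was 0.771, below the 0.845 to 0.882 of the other disc arrays. That lower mean alone does not decide, because D1 also had the lowest mean correlation with the disc arrays (0.877). Slower proliferation in D1 was argued against too, because its proliferation list had a median deviation of 1.03, above those of 5 of the other 6 disc cultures. A difference at the level of probe sets, such as RNA quality or amplification, may account for part of the pattern, since deviations of 2 probe sets of the same gene correlated at 0.251 in D1 and at 0.64 to 0.78 in the others (2221 genes, not independent replicates). Other differences between the cultures themselves stay open, as proliferation was the biological explanation tested.

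Transcripts of leukocyte markers were far higher in AD-MSC than in disc arrays. Of 34 tested genes of a second macrophage list, 94.1% were lower in disc cells than in controls, which is consistent with macrophages carried along in the AD-MSC cultures, while none of the list is also in the fixed lists and 3 of 39 on the array had a disc mean over 8. Its most abundant genes averaged 14.6 in controls and 10.9 in disc cells for GPNMB, 11.9 and 9.33 for RAC2, and 11.2 and 8.69 for TNFSF13B. A general rise of transcripts foreign to the main cell type stays open: the median difference of a lymphocyte list lay 2.58 log2 units above that of the macrophage list, but most of its genes were near the floor (median level 3.47 in controls and 3.42 in disc cells), and of the 6 tested 1 was lower and 1, IL7R, was higher. Mast cells could not be settled, as 71.4% of 7 tested genes of a mast cell list were lower (KIT the most abundant, at 10.3 in controls and 6.08 in disc cells), between the bounds of 50% and 80%, and expression of such genes by the AD-MSC themselves was not tested.

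As a list, leukocyte markers fell with TGF-β3 in AD-MSC (adjusted p = 2.2e-15, and adjusted p = 0.068 with an estimated correlation), with 4 of 19 passing. A lower share of leukocytes as the whole cause would lower their abundant genes alike, yet over 10 macrophage genes with a control mean above 8 the SD of the TGF-β3 effects was 3.23 times their median SE, over a bound of 2. None of the 10 passed in limma on 13 arrays and 5 did with the culture as a block, with log2 changes from -2.82 for TNFSF13B to -0.30 for GPNMB and a median of -1.90. The ratio was 2.5 to 3.75 with any 1 gene left out and 2.82 over the 7 genes with a disc mean up to 8, but 1.70 without the 2 smallest falls (GPNMB and APOC1), and genes low in disc cells moved apart too, with -2.19 for C1QA (SE 0.28), -0.03 for LYZ (SE 0.45) and 1.43 for CCL18 (SE 0.29). A lower share may account for part of the fall, and a change of expression within the macrophages or in the AD-MSC stays open, as TGF-β3 is the treatment that the design names.

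Other splits of the same arrays into groups of the same sizes were counted. For disc cells against controls the real split gave 3124 genes and the other 99 of 100 splits drawn at most 9. For disc cells against TGF-β3 AD-MSC these were 3419 and at most 53. In both, 1 split gave as many, a share of 1%, which argues against a chance labelling of these arrays. Splits that mix disc cells with AD-MSC put any difference between them into the spread, which lowers their counts. Causes that go with cell type here, such as time in culture or an unknown batch, were not tested by the splits. For TGF-β3 against control AD-MSC the 10 splits were too few for a share under 0.05, the real split giving 122 genes and the highest other 4. Only 1 split, the real one, gave as many, and among the 4 splits that part all 3 pairs the highest other gave 0 genes.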

How the results depend on the processing

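The distance analyses on genes higher or lower in disc cells, the list tests with the culture block on 6 arrays, and the count without marker genes were chosen after seeing the data. Of 99 named gene results that passed, 79 kept direction and call in every alternative in which the gene was tested, 20 were lost in at least 1, and none changed sign. Alternatives that removed a gene were not counted as a loss for it, FCGBP, RCSD1 and CD209 with TGF-β3 and CCN6 among those concerned. Stricter thresholds were applied to the gene counts only. Of 28 that did not pass, 19 passed in at least 1. Of 32 list calls, 4 held in every alternative and 28 were lost in at least 1, none changing direction, and 14 of 34 uncalled lists were called in at least 1. The culture block changed no calls of the genes and lists named beyond those given with the TGF-β3 comparison, below and among the other observations. The cause of the changes below was not tested, except that stricter thresholds give fewer calls by construction. Fits on fewer arrays gave fewer calls in some cases and more in others. No pseudocount was tried, as the values are already logarithms.

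For genes changed by TGF-β3 (122, of which 32 higher and 90 lower), the culture as a replicate block gave 574 (152 and 422) on 6 arrays and 642 (177 and 465) by duplicateCorrelation on 13 arrays, where the nucleus pulposus list was called for TGF-β3, the bone, cartilage and inflammatory lists for disc against TGF-β3, and the collagen, contractile, HOX and proliferation calls of disc against control were lost. Without the block, the 4 lists gained had adjusted p = 0.17, 0.32, 0.51 and 0.55 with an estimated correlation. Array weights gave 804 (277 and 527), a mean above the 60th percentile 22 (5 and 17), adjusted p under 0.01 45 (12 and 33), and only the 2 groups compared 94 (54 lower), of which 38 were among the 122. Leaving out arrays or cultures gave 42 to 211 genes, with 8 (without culture B) to 50 (without D1) higher and 34 (without culture B) to 180 (without control A) lower. Higher counts also moved over 1.5 times without control B (14), treated B (15), control C (17), treated C (18), D3, D4 or D6 (20 each) and culture C (14), and lower counts without control B (48), treated B (43), D3 or D4 (59 each), culture A (145) and culture C (50).

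For disc cells against controls (3124, 1283 higher and 1841 lower), adjusted p under 0.01 gave 1520 (509 and 1011), array weights 1957 higher, and at least 2-fold 837 higher. Leaving out 1 array gave 1744 (without control C) to 3876 (without D1) genes, 607 to 1572 higher and 1137 to 2304 lower, both lowest without control C. Higher genes were 701 without control A and 823 without control B. Taking the leukocyte, macrophage and endothelial list genes out of the 3124, without a new fit, left 3067. This count does not measure the part of carried-along cells, since leukocyte genes outside the lists, such as PLEK, stayed in. For disc cells against TGF-β3 AD-MSC (3419, 1510 and 1909), adjusted p under 0.01 gave 1577 (648 and 929) and array weights 6802 (3053 and 3749). Leaving out 1 array gave 1879 (without treated C) to 4237 (without D1) genes, 807 to 1792 higher and 1072 to 2445 lower, both lowest without treated C, and 942 higher without treated A. Quantile normalization shifted the median of all genes by 0.10 in disc against control and by 0.11 in disc against TGF-β3. The number of list calls was 4 with estimated correlation against 32, and 28 to 33 in leave-outs.

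The mean change in distance (-5.95) was -18.6 over genes called between disc cells and the other controls, -22.8 over those called lower in disc cells (covariance 0.85) and 1.12 over those called higher (SD 4.78, covariance 0.044), where culture B alone gave a distance above 0 (6.53) and a covariance below 0 (-0.17). Leaving out 1 array gave -10.1 to -3.05, the stricter filter gave -1.23 and no filter gave -7.97. The covariance (0.25) was 0.19 with no filter, with the stricter filter, with every probe set and with the mean of probe sets, 1.24 over called genes, and 0.20 (without control B) to 0.29 (without control A) with 1 array left out. With the mean of a gene's probe sets, 24 of 97 passing gene results shrank over 1.5 times on the log2 scale, none grew so much, 2 were lost (CDK1 with TGF-β3 among them, -1.45, adjusted p = 0.083) and the median ratio was 0.975. Lowest were MMP11 (-1.05 and -1.19 in the disc comparisons) and, among other genes named, IL1RN (-2.48) and ZIC1 (3.84 and 3.89). Some genes with changes near 0 changed sign. DCN with TGF-β3 had -0.0072 with quantile normalization, -0.072 with the mean of probe sets, and -0.083 to 0.12 in leave-outs. COL1A1 with TGF-β3 had -0.0071 with array weights and -0.097 to 0.16 in leave-outs. COL1A1 in disc against control had 0.0052 with quantile normalization, 0.052 with median centring, and -0.12 to 0.10 in leave-outs. In disc against TGF-β3 it had -0.15 to 0.076 in leave-outs, above 0 without treated A. With the mean of its probe sets COL1A1 passed in both, at -1.49 (adjusted p = 0.0066) and -1.55 (adjusted p = 0.0052).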

Other observations

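The values of CCL18, and of HAPLN1 and MATN3 in disc cells against TGF-β3 AD-MSC, were chosen after they were seen. Further genes did not pass for TGF-β3 in the limma fit on 13 arrays but passed with the culture as a block on the 6 AD-MSC arrays. EPYC, a proteoglycan gene of growth cartilage, had a log2 change of 4.54 (SE 1.11, adjusted p = 0.091, and 0.014 with the culture as a block, n = 3 cultures), from a control mean below 4.21, the median of all values. CILP2 had 2.71 (SE 0.61, adjusted p = 0.062 and 0.024 with the block), the signal transducer gene SMAD9 had 2.07 (SE 0.47, adjusted p = 0.062 and 0.021), and ENPP1, which makes pyrophosphate, had 2.82 (SE 0.73, adjusted p = 0.11 and 0.018, but 1.52 with the mean of its probe sets). CHI3L1 had -3.23 (SE 0.70, adjusted p = 0.051 and 0.016). NUSAP1, a mitotic spindle gene, had -2.51 (SE 0.67, adjusted p = 0.12 and 0.038). CCL18, a chemokine of macrophages, rose by 1.43 on the log2 scale (SE 0.29, adjusted p = 0.043), while most leukocyte genes named fell.

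In disc cells against controls, the ribonuclease gene RNASE1 had a log2 difference of -9.29 (SE 0.41, and -4.57 with the mean of its probe sets) and PLEK, a platelet and leukocyte gene, had -8.69 (SE 0.46). Against TGF-β3 AD-MSC, disc cells had -8.18 for SPON2 (SE 0.60), -8.29 for CXCR4 (SE 0.44, and -4.76 with the mean of its probe sets) and 7.31 for FGFBP2 (SE 1.21). Means were below 4.21, the median of all values, in disc cells for RNASE1, PLEK and CXCR4 and with TGF-β3 for FGFBP2. HAPLN1 was higher in disc cells than in TGF-β3 AD-MSC by 3.72 and MATN3 had -3.55. When every probe set was tested on its own (26961 probe sets), 0 genes had probe sets called in both directions with TGF-β3. Such genes numbered 92 in disc cells against controls, MMP2 among them, and 95 in disc cells against TGF-β3 AD-MSC, TNC and SYNPO2 among them.

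Endothelial cells carried along in the AD-MSC cultures were a further hypothesis for the endothelial transcripts there. Of 18 tested genes of a second endothelial list, 55.6% were lower in disc cells than in controls, between the bounds of 50% and 80%, so the test left the hypothesis open. Its most abundant gene was APLN, at 10.7 in controls and 9.56 in disc cells, and 2 of the 22 genes on the array had a disc mean over 8, against 5 in controls.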
